A study of Mus musculus with 6 samples.

How the data were processed

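Messenger RNA was sequenced from in vitro generated germinal centre B cells of wild-type C57BL/6J mice, in 3 libraries treated with the solvent DMSO and 3 treated with the GSK3 inhibitor CHIR99021. Per the labels' protocols, naive follicular B cells grew for 4 days with IL-4 at 1 ng/ml on feeder cells that express CD40L, and were then treated for 36 h on such feeder cells with IL-21 at 10 ng/ml. The labels give 3 uM for the CHIR99021 dose and print the same figure beside DMSO. Per the labels' protocols, the treated cells were purified before RNA extraction with an RNeasy kit, and libraries were made with the TruSeq Stranded mRNA kit. How the cells were purified is not given in the sources used here.

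Per the submitters' processing notes, cutadapt 1.12, TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse genome build mm10 were used. The annotation, the strand setting, the treatment of reads with several matches and the total that Cufflinks divided by are not given in the sources used here. The authors deposited 1 table per library, which per the file headers holds a gene FPKM (fragments scaled for transcript length and for library total) with its lower and upper confidence limits and an estimation status. Each table holds 23850 gene entries with 23356 distinct symbols, and 754 entries share a symbol with another entry, of which 16 were among the tested genes. Every status was given as OK. Coordinates are the gene spans of the deposited tables on mm10, with starts converted to count from 1. Immunoglobulin constant region genes and mitochondrially encoded genes were not analysed here.

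FPKM are not counts, so no count model was used and the number of sequenced fragments per library is not stated. The summed FPKM per library was 617449, 527290 and 601991 for DMSO replicates 1, 2 and 3, and 616427, 556644 and 615622 for CHIR99021 replicates 1, 2 and 3. The precision that the depth allowed was read from the Cufflinks confidence limits: the median tested gene had limits 12.5% to 15.4% of its FPKM away from its value, depending on the library, which covers the uncertainty of a single library and not the spread between cultures. Between 13418 and 14429 gene entries per library had a value above 0. An FPKM depends on the annotated transcript length and on the other transcripts of the library, so genes with near-identical copies, such as the Bcl2a1 genes, the ribosomal protein genes and the histone genes, and genes that overlap others are less certain than the rest.

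Libraries were grouped by the treatment in the labels, and the series describes the design as biological triplicates. FPKM were transformed to log2(FPKM + 1), and the 10096 genes with a mean of 1 FPKM or more over the 6 libraries were tested for CHIR99021 against DMSO with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend). All p-values are two-sided, and adjusted p-values are by Benjamini-Hochberg with a threshold of 0.05. Every log2 change is on the log2(FPKM + 1) scale, which understates the change of genes of low level, while folds are ratios of mean FPKM without the pseudocount. Genes changed at least 2-fold passed the same threshold and had an absolute log2 change of 1 or more. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.

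Before the data were examined, 18 key genes and 36 gene lists were fixed, together with the test, the other settings to be tried and the rule for naming genes. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists that qualified. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction without comparing them with other genes, were run beside it. The named genes are the key genes, the 10 genes with the largest rise and the 10 with the largest fall, and up to 4 members of each list with the smallest adjusted p under 0.05. The genes with the largest changes had to pass the test, reach a mean of 5 FPKM in the higher group and have no overlap between groups, and predicted genes, gene segments and small RNA genes were passed over. Outside this rule, Ezh2, Lgmn, Cd2, Lck, Cybb, Cd3e, Col1a1, Tnfsf13b and Eif2s3y were named after their values were seen. The same holds for Cd14, Csf1r, S100a8, Cd3d, Cd4, Cd8a and Cd40lg, for the genes given as members of families chosen later, and for Pdcd1 and Tigit. A few genes that the rule names are not reported here. Of the list genes, 4 were found under older symbols. The lists of T cell markers (4 of 16 members tested), of ligands expressed by the feeder cells (1 of 2 tested), of immunoglobulin constant region genes and of mitochondrially encoded genes had too few tested members for a list test.

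The titles number the replicates 1 to 3 in both groups. The deviations of each library's log2 values from its group mean correlated across genes at 0.535, 0.490 and 0.517 for libraries of the same number, against -0.352 to -0.140 for libraries of different numbers. The Y-linked gene Eif2s3y had 26.5 FPKM in DMSO replicate 3 and 25.4 FPKM in CHIR99021 replicate 3, and at most 0.116 FPKM in the other 4 libraries. The numbers therefore pair the libraries. The pairing comes from the data and the titles, since the labels do not say what a number stands for. Xist, a transcript of female cells, had 10.1 and 39.5 FPKM in DMSO replicates 1 and 2 and 15.6 and 36.0 in CHIR99021 replicates 1 and 2. It was at 0 in replicate 3 of both groups. Replicate 3 therefore had the pattern of male cells and replicates 1 and 2 that of female cells. A fit without a replicate block leaves this difference in its spread. The design fixed beforehand had no replicate block, and the fit with the block is an alternative.

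On simulated data made from the spread of these libraries, in 5 draws of the 10096 genes of CHIR99021 against DMSO with 100 genes changed per size, the test recovered 82.8% of genes changed by 1 on the log2 scale and 14.2% of genes changed by 0.5, with 4.99% of its calls false. A simulated list that moved was called in 5 of 5 draws, and 0 of 20 unchanged lists per draw were called. The draws were independent between libraries and genes, so they hold neither the pairing nor the correlation of genes, and the fit had no block. They also held far fewer changed genes than the 2164 called in the data. The Benjamini-Hochberg limit was therefore stricter in the draws, so their recovery may understate that in the data. Settings chosen beforehand were pseudocounts of 0.1 and 5, no filter on level and a mean of 5 FPKM or more, median-of-ratios, upper-quartile and quantile scaling, no variance trend, a robust variance prior, library weights, the replicate block, leaving out each library, a threshold of 0.01, and the 2 other list tests. Settings chosen after seeing the data were the level of feeder cell markers as a covariate, leaving out both libraries of a replicate number, and a correction of each library for GC content and transcript length, alone and with the block. GC content and length came from the longest transcript of each symbol in GENCODE vM21 and were found for 10029 tested genes (99.3%) and for 100% of the tested members of every list.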

Results

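The transcriptomes of 6 cultures of in vitro generated germinal centre B cells were compared, 3 treated with CHIR99021 and 3 with DMSO. Germinal centre B cells are the activated, dividing B cells in which antibody genes are mutated and selected, and the cells here were made from naive follicular B cells by CD40 ligand and IL-4, followed by IL-21. CHIR99021 is a small-molecule inhibitor of the kinases GSK3A and GSK3B, and the series asks how the expression profile of these cells differs when GSK3 is inhibited. Levels are FPKM with the SD over 3 libraries (n = 3 per group), and adjusted p-values are from limma's test over all genes tested. Across all tested genes, log2 values of libraries within a group correlated at 0.970 to 0.980, and those of libraries from different groups at 0.942 to 0.967. No pair of libraries was a duplicate, since at most 0.228% of the values of a pair were identical.

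With CHIR99021, the lists of pan B cell markers, MHC class II antigen presentation and light zone genes were called lower by camera at its preset correlation, and those of ribosome biogenesis, the amino acid response, the unfolded protein response and the plasma cell programme higher. None of these lists was called with an estimated correlation (adjusted p = 0.284 to 0.367). Of 10096 tested genes, 2164 changed (21.4%), with 821 higher and 1343 lower in CHIR99021, and 379 of them changed at least 2-fold, with 101 higher and 278 lower. The 2-fold count depended on the pseudocount, at 520 with 0.1 and 159 with 5. Among the genes that rose most were Cd28, a costimulatory receptor (0.256 ± 0.120 to 9.53 ± 1.95 FPKM), and Plac8 (5.52 ± 2.95 to 45.1 ± 13.2). They also included the transcription factor genes Tcf7 (5.68 ± 0.364 to 29.3 ± 7.01) and Myb (4.88 ± 1.82 to 23.6 ± 5.75) and the chemokine receptor gene Cxcr7 (5.16 ± 2.64 to 21.3 ± 4.70). Cntnap1, Atp1b1, Rgs16, Bco2 and Crhbp completed the 10 largest rises among genes that met the naming rule, with log2 changes from 1.90 to 2.44. The largest falls included Il4i1, a secreted amino acid oxidase induced by IL-4 (163 ± 11.2 to 26.7 ± 2.83 FPKM, 6.08-fold lower). Others were Ccr6, a chemokine receptor (240.3 ± 13.8 to 48.7 ± 2.40, 4.93-fold lower), and Fcer2a, the low-affinity IgE receptor CD23 (114 ± 23.8 to 23.7 ± 5.86, 4.83-fold lower). Serpinb1a, Hbb-bh1, Ffar2, Scimp, Crip1 and Sorl1 also belonged to the 10 largest falls, with log2 changes from -2.68 to -2.21. Each of the genes named here moved the same way in 3 of 3 replicate numbers, which follows from the rule that the groups not overlap. Their adjusted p ran from 4.61e-05 to 0.00512, and passing the test was part of the same rule.

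**Figure D1:**
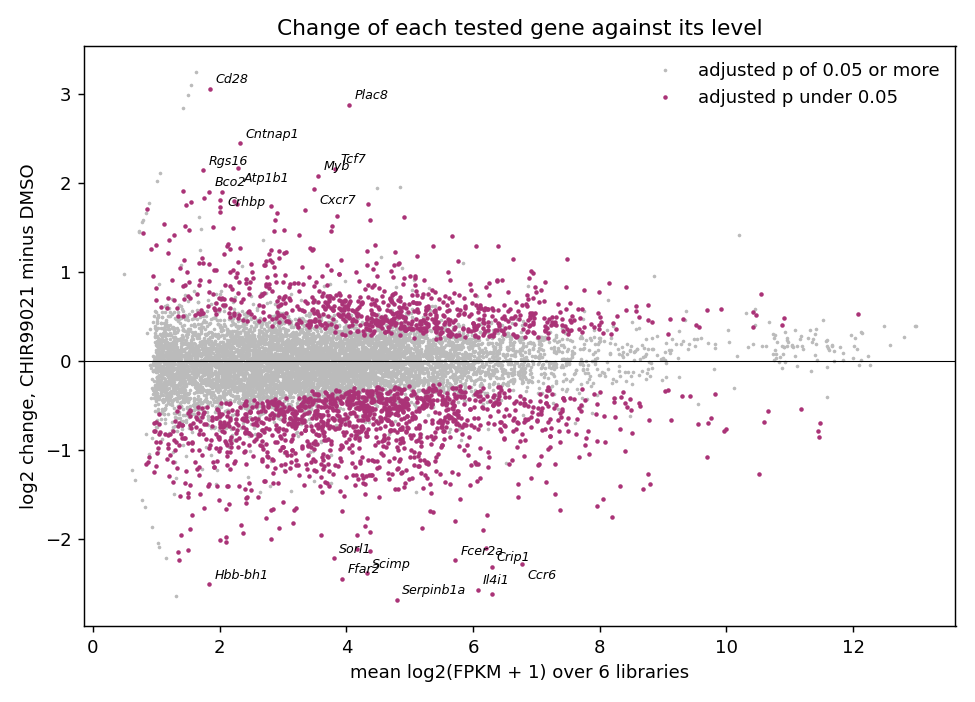
Log2 change of each of the 10096 tested genes (CHIR99021 minus DMSO, vertical axis) against its mean log2(FPKM + 1) over the 6 libraries (horizontal axis), with the 2164 genes at an adjusted p under 0.05 in colour and genes among the 10 largest rises and 10 largest falls named. Of the coloured genes, 821 lie above 0 and 1343 below.

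The groups did not overlap for 4047 genes (40.1%), against 10% by chance if the 6 libraries were exchangeable, which their pairing by replicate number does not meet. With the replicate number as a block, 4321 genes changed, 1855 higher and 2466 lower, including all 2164 genes called without it, each in the same direction. The split by direction depended on the scaling between libraries: 37.9% of the calls were higher with FPKM as deposited, against 48.7% with upper-quartile and 51.2% with quantile scaling. Leaving out DMSO replicate 3, CHIR99021 replicate 2 or CHIR99021 replicate 3 left 1310, 1410 and 1061 genes changed.

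Of the 18 key genes, 17 were tested and 6 changed, or 8 when adjusted over the list alone and 10 with the replicate block. The partners of beta-catenin at its target genes, Tcf7 and Lef1, both rose. Tcf7 (chromosome 11, 52252604 to 52282571) rose by 2.16 ± 0.16 (SE) on the log2 scale (adjusted p = 0.000435). Lef1 (chromosome 3, 131110297 to 131224357) rose from 8.504 ± 0.519 to 15.2 ± 1.32 FPKM (log2 change 0.77 ± 0.11 SE, adjusted p = 0.00286). The transcription factor gene Irf4 (chromosome 13, 30749258 to 30766927), which promotes plasma cell differentiation, rose from 30.5 ± 2.04 to 82.1 ± 8.01 FPKM (log2 change 1.40 ± 0.10 SE, adjusted p = 0.000431). Prdm1 (chromosome 10, 44437175 to 44458687), which encodes the plasma cell regulator BLIMP1, rose from 6.27 ± 1.499 to 16.2 ± 2.74 FPKM (log2 change 1.25 ± 0.18 SE, adjusted p = 0.00347). The B cell identity factor gene Pax5 (chromosome 4, 44531506 to 44710440) was 1.93-fold lower, at 54.6 ± 3.74 and 28.3 ± 1.92 FPKM (log2 change -0.92 ± 0.09 SE, adjusted p = 0.000736). Bach2 (chromosome 4, 32417435 to 32586108), which encodes a repressor of Prdm1, was 5.41-fold lower, at 9.10 ± 0.695 and 1.68 ± 0.431 FPKM (log2 change -1.92 ± 0.15 SE, adjusted p = 0.000479).

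For 4 further key genes the call depended on the fit. The beta-catenin gene Ctnnb1 had 99.5 ± 7.96 and 82.9 ± 3.64 FPKM in DMSO and CHIR99021 (adjusted p = 0.0704, or 0.00941 with the replicate block). Xbp1 had 129 ± 4.12 and 153 ± 7.01 FPKM (adjusted p = 0.0567, or 0.0172 with the block). These were also the genes added when the test was adjusted over the list alone. Bcl6, the master regulator of germinal centre B cells, had 7.18 ± 2.23 and 4.55 ± 1.72 FPKM (adjusted p = 0.160, or 0.00307 with the block). Ccnd2 had 46.3 ± 6.78 and 54.1 ± 8.33 FPKM (adjusted p = 0.316, or 0.0206 with the block). Other tested key genes did not pass in either fit. Gsk3a had 62.2 ± 2.49 and 64.7 ± 1.94 FPKM, Gsk3b 5.32 and 4.26, and Myc 37.1 ± 7.82 and 38.05 ± 4.85. Sdc1 had 5.09 and 4.12, Ccnd3 57.8 and 51.3, and Foxo1 17.8 and 19.0. Axin2, a beta-catenin target and feedback inhibitor, lay below the limit on level, at 0.0354, 0 and 0.0846 FPKM in the DMSO libraries and 0.284, 0.354 and 0.607 in the CHIR99021 libraries. Without that limit it was called higher (log2 change 0.44, adjusted p = 0.0321).

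**Figure D2:**
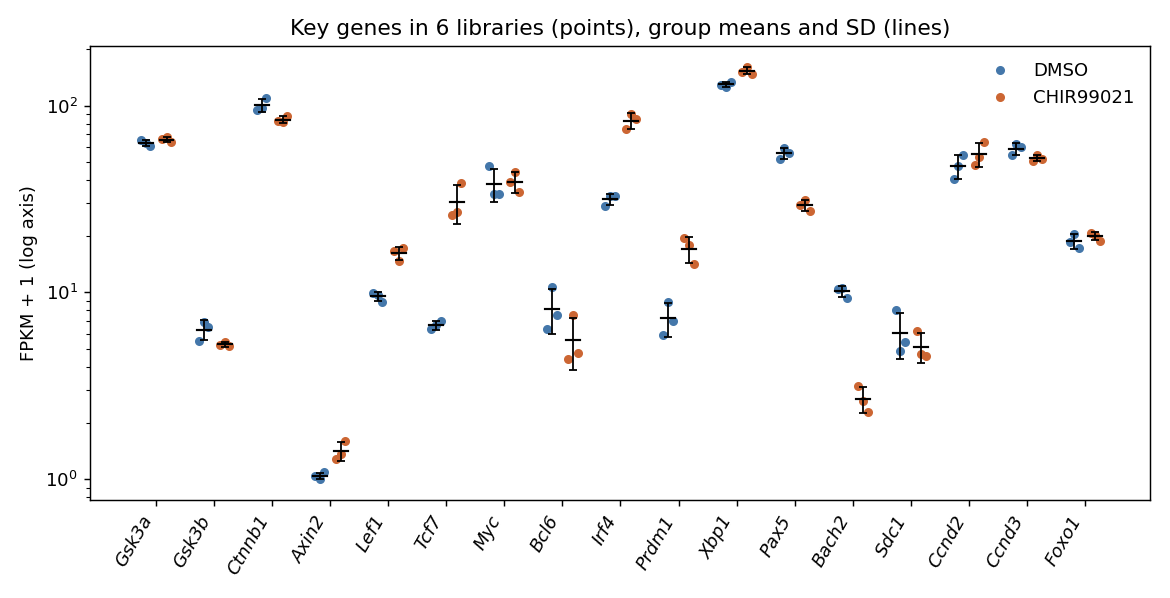
FPKM + 1 (log axis) of key genes in each library (points, 3 per group), with group means (horizontal lines) and SD (error bars). The 3 CHIR99021 libraries lie above the 3 DMSO libraries for Tcf7, Lef1, Irf4 and Prdm1 and below them for Pax5 and Bach2.

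Among 9 tested Wnt/beta-catenin target genes, Lef1 and Tcf7 rose and Cd44 fell (58.5 ± 5.31 to 45.0 ± 1.92 FPKM), with the same counts when adjusted over the list alone. The list as a whole was not called by camera (median log2 change 0.04, adjusted p = 0.461), though it was without the limit on level (0.0375) and by fry (0.0228, but 0.0707 with the replicate block). The fall of Cd44 (adjusted p = 0.0258) was not called without DMSO replicate 3 (0.0795) or without CHIR99021 replicate 1, 2 or 3 (0.0784, 0.0621 and 0.0790). Of 12 genes for GSK3 and the beta-catenin destruction complex, 2 fell and 0 rose, also over the list alone. The list was not called by camera (adjusted p = 0.0741), though it was without DMSO replicate 1 (0.0289), without the limit on level (0.0215) and by fry (0.0079). The genes that fell were Frat1 and Frat2, which encode GSK3-binding proteins. Frat1 had 4.93 ± 0.575 and 0.363 ± 0.104 FPKM (13.6-fold lower, adjusted p = 0.000431) and Frat2 had 4.17 ± 0.122 and 0.346 ± 0.131 FPKM (12.05-fold lower, adjusted p = 0.000455).

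Of 13 pan B cell markers, 11 fell and 0 rose, also when adjusted over the list alone. Pan B cell markers had a median log2 change of -1.07 (camera adjusted p = 1.81e-06), and adjusted p = 0.284 with an estimated correlation. Besides Fcer2a, these included Ms4a1, which encodes CD20 (520.3 ± 77.8 to 195 ± 7.24 FPKM), Cd37 (679 ± 120.2 to 248 ± 8.78) and Cd22, an inhibitory receptor of B cells (228 ± 22.4 to 88.9 ± 13.04). Of 27 genes of the germinal centre B cell programme, 14 fell and 1 rose, or 14 and 4 when adjusted over the list alone. The germinal centre programme had a median log2 change of -0.49 (camera adjusted p = 0.00201), and adjusted p = 0.284 with an estimated correlation. Those that fell included Bach2 and the transcription factor genes Lmo2 (151 ± 12.8 to 34.6 ± 4.62 FPKM), Spib (298 ± 47.0 to 92.4 ± 4.49) and Irf8 (197 ± 7.16 to 109.5 ± 3.90). The gene that rose, named here after its value was seen, was the histone methyltransferase gene Ezh2 (60.4 ± 5.21 to 113 ± 1.91). Of 17 memory B cell associated genes, 8 fell and 0 rose, or 12 fell when adjusted over the list alone and 13 with the replicate block. Memory B cell associated genes had a median log2 change of -0.55 (camera adjusted p = 1.03e-05), and adjusted p = 0.338 with an estimated correlation. Ccr6, Bach2 and the transcription factor gene Hhex (43.0 ± 6.89 to 8.98 ± 1.31 FPKM) were among them.

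Of 28 genes of the plasma cell programme, 9 rose and 2 fell, or 13 and 2 when adjusted over the list alone and 17 and 4 with the replicate block. The plasma cell list had a median log2 change of 0.29 (camera adjusted p = 6.22e-05), and adjusted p = 0.338 with an estimated correlation. Besides Irf4, Prdm1 and Cd28, the transcription factor gene Bhlha15, a regulator of secretory cells, rose from 3.57 ± 0.502 to 9.48 ± 1.15 FPKM (adjusted p = 0.00147). The surface receptor gene Slamf7 rose from 17.9 ± 3.72 to 38.4 ± 3.97 (adjusted p = 0.00341). Sdc1, which encodes the plasma cell marker CD138, did not pass the test (5.09 and 4.12 FPKM, adjusted p = 0.510). Of 29 genes of the unfolded protein response and the chaperones of the endoplasmic reticulum, 12 rose and 0 fell, or 17 higher over the list alone and 20 higher and 1 lower with the block. Genes of the unfolded protein response had a median log2 change of 0.32 (camera adjusted p = 2.91e-06), and adjusted p = 0.338 with an estimated correlation. Examples were the stress sensor gene Ern1 (2.24 ± 0.499 to 6.76 ± 0.379 FPKM) and the chaperone gene Hyou1 (55.2 ± 6.22 to 102 ± 5.62). Others were the translocon genes Sec61a1 (93.8 ± 11.0 to 168 ± 9.96) and Ssr3 (92.8 ± 5.36 to 143 ± 9.51).

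Light zone genes, which mark germinal centre B cells that present antigen and receive T cell help, fell for 16 of 22 members and rose for Myb alone, or for 18 and 1 when adjusted over the list alone. Light zone genes had a median log2 change of -0.61 (camera adjusted p = 4.01e-07), and adjusted p = 0.284 with an estimated correlation. The receptor gene Slamf1 had 34.3 ± 1.499 and 8.23 ± 1.77 FPKM and Cd83 93.8 ± 13.03 and 41.0 ± 4.95. For MHC class II antigen presentation, 12 of 13 genes fell and 1, the protease gene Lgmn, rose (adjusted p = 0.0423), with the same counts over the list alone. MHC class II genes had a median log2 change of -0.82 (camera adjusted p = 7.07e-06), and adjusted p = 0.367 with an estimated correlation. Those that fell included the lysosomal reductase gene Ifi30 (543 ± 88.3 to 159.8 ± 13.8 FPKM), H2-DMb2 (325 ± 34.4 to 158 ± 15.8), H2-Ob (60.8 ± 5.22 to 28.6 ± 4.78) and the transactivator gene Ciita (32.3 ± 2.25 to 16.2 ± 2.17). Of 24 NF-kappaB and CD40 response genes, 14 fell and 1 rose, or 15 and 1 over the list alone. NF-kappaB and CD40 response genes had a median log2 change of -0.41 (camera adjusted p = 1.26e-05), and adjusted p = 0.284 with an estimated correlation. The chemokine gene Ccl22 had 67.1 ± 7.87 and 23.5 ± 4.80 FPKM and the adaptor gene Traf1 36.8 ± 4.30 and 16.3 ± 0.322. The IL-2 receptor gene Il2ra rose from 1.63 ± 0.123 to 7.98 ± 1.47. Dark zone genes, which mark the dividing and mutating germinal centre compartment, were not called as a list (median -0.07, adjusted p = 0.888). Of 20 members 2 rose, which were Cxcr4 (24.6 ± 5.88 to 44.8 ± 5.10 FPKM) and the DNA ligase gene Lig4 (1.81 ± 0.676 to 5.36 ± 0.558). A further 3 fell, or 5 over the list alone, among them Stmn1 (265 ± 58.8 to 149 ± 11.9).

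Of 15 STAT3 and IL-21 response genes, 8 fell and 1, Prdm1, rose, or 8 and 2 over the list alone. STAT3 and IL-21 response genes had a median log2 change of -0.40 (camera adjusted p = 0.0298), and adjusted p = 0.320 with an estimated correlation. Il4ra had 42.0 ± 4.41 and 17.7 ± 1.23 FPKM, Il21r 237 ± 12.8 and 137 ± 8.55, and Junb 338 ± 11.6 and 181 ± 12.6. This list was not called with the replicate block (adjusted p = 0.0910), without DMSO replicate 3 (0.0628) or without CHIR99021 replicate 2 (0.0663). The GC content and length correction, with or without the block, also ended its call. Of 19 FOXO target genes, 8 fell and 1, Cxcr4, rose, or 10 and 1 over the list alone. FOXO target genes had a median log2 change of -0.51 (camera adjusted p = 0.00127), and adjusted p = 0.471 with an estimated correlation. The genes that fell included Ccng2 (30.2 ± 5.04 to 11.1 ± 2.28 FPKM), the PI3K inhibitor gene Pik3ip1 (10.3 ± 2.33 to 3.66 ± 0.315) and Irs2 (10.9 ± 2.45 to 4.25 ± 0.454). Of 19 mTORC1 and PI3K pathway components, 5 fell and 1 rose, also over the list alone, and the list was not called (median -0.06, adjusted p = 0.344). The PI3K adaptor gene Pik3ap1 had 49.96 ± 5.72 and 23.5 ± 3.10 FPKM and the kinase gene Akt2 65.3 ± 5.54 and 40.8 ± 2.07. Of 11 type I interferon response genes, 1 rose and 2 fell, or 1 and 4 over the list alone (median -0.34, adjusted p = 0.137). Bst2 had 26.7 ± 4.68 and 42.3 ± 4.64 FPKM. The interferon list was called lower without CHIR99021 replicate 1 (adjusted p = 0.0304).

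Of 38 MYC target and ribosome biogenesis genes, 25 rose and 0 fell, or 37 and 0 when adjusted over the list alone. MYC targets had a median log2 change of 0.57 (camera adjusted p = 6.41e-14), and adjusted p = 0.338 with an estimated correlation. Nucleophosmin, Npm1, rose from 1149.6 ± 51.0 to 1947 ± 136 FPKM (adjusted p = 0.00277) and the spermidine synthase gene Srm from 85.4 ± 17.5 to 171 ± 21.5 (0.00542). So did the nucleolar protein gene Nop58 from 80.8 ± 9.90 to 128 ± 8.52 FPKM (0.00488), and the ribosome maturation gene Nob1 from 19.9 ± 1.57 to 34.5 ± 1.38 (0.00148). Myc itself, a member of this list, had a log2 change of 0.05 ± 0.16 (SE) and an adjusted p of 0.877. Of 27 genes of the ATF4 amino acid response, 15 rose and 0 fell, or 18 and 1 over the list alone. ATF4 response genes had a median log2 change of 0.47 (camera adjusted p = 4.01e-07), and adjusted p = 0.284 with an estimated correlation. Asparagine synthetase, Asns, rose from 22.2 ± 1.17 to 51.5 ± 4.202 FPKM and the serine synthesis gene Psat1 from 88.5 ± 1.17 to 149 ± 1.82. Cth rose from 4.14 ± 0.693 to 10.5 ± 0.900 and Shmt2 from 96.4 ± 8.64 to 166 ± 11.8.

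In central metabolism, nuclear encoded oxidative phosphorylation genes rose for 9 of 50 members with 0 lower, or 5 and 0 when adjusted over the list alone and 20 and 2 with the replicate block. Oxidative phosphorylation genes had a median log2 change of 0.12 (camera adjusted p = 0.00092), and adjusted p = 0.602 with an estimated correlation. The complex III gene Uqcrfs1 had 76.6 ± 5.69 and 106 ± 4.59 FPKM. Of 21 glycolysis genes, 2 rose and 0 fell, also over the list alone, with 15 higher and 2 lower with the block. Glycolysis genes had a median log2 change of 0.41 (camera adjusted p = 0.00292), and adjusted p = 0.599 with an estimated correlation. The genes that rose were the phosphofructokinase gene Pfkp (17.1 ± 4.28 to 40.9 ± 7.18 FPKM) and the lactate transporter gene Slc16a1 (19.4 ± 2.70 to 33.0 ± 2.32). Without DMSO replicate 2, neither oxidative phosphorylation (adjusted p = 0.0612) nor glycolysis (0.0661) was called, and fry called neither (0.195 and 0.197), or both with the block (0.0427 and 0.0295). Of 18 HIF-1 target genes, 2 rose and 1 fell, or 6 and 1 over the list alone and 10 and 3 with the block. HIF-1 target genes had a median log2 change of 0.29 (camera adjusted p = 0.0382), and adjusted p = 0.602 with an estimated correlation. Vegfa (12.1 ± 1.91 to 29.9 ± 3.68 FPKM) and the oxidoreductase gene Ero1l (18.6 ± 3.57 to 40.8 ± 8.12) rose. The HIF-1 list was not called by fry (0.247, though 0.0178 with the block), without DMSO replicate 1 (0.0535), DMSO replicate 2 (0.217), CHIR99021 replicate 1 (0.0583) or CHIR99021 replicate 3 (0.115), with library weights (0.115) or the feeder covariate (0.0747), or with median-of-ratios (0.0693), upper-quartile (0.0779) or quantile scaling (0.0879). Cholesterol biosynthesis genes fell for 9 of 24 members with 0 higher, or 11 over the list alone and 16 with the block. Cholesterol biosynthesis genes had a median log2 change of -0.29 (camera adjusted p = 0.000568), and adjusted p = 0.443 with an estimated correlation. Examples were Fdft1 (34.2 ± 1.13 to 24.1 ± 0.904 FPKM) and Mvd (60.7 ± 4.62 to 41.6 ± 1.75). Glycogen metabolism, the classical pathway of GSK3 through glycogen synthase, had 0 of 12 genes called, also over the list alone (median -0.10, adjusted p = 0.911). Lysosome and autophagy genes were not called as a list (median -0.07, adjusted p = 0.570). Of its 28 genes 2 rose and 6 fell, or 2 and 7 over the list alone. The lysosomal protease gene Ctsa (62.3 ± 6.96 to 32.0 ± 2.89 FPKM) and the autophagy gene Uvrag (60.5 ± 1.40 to 36.0 ± 2.82) fell.

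Of 28 G2/M and mitosis genes, 8 fell and 0 rose, also over the list alone, with 13 lower with the replicate block. G2/M and mitosis genes had a median log2 change of -0.15 (camera adjusted p = 0.00861), and adjusted p = 0.367 with an estimated correlation. Examples were the mitotic kinesin gene Kif23 (46.5 ± 3.07 to 28.9 ± 2.41 FPKM) and the kinase gene Nek2 (42.8 ± 2.75 to 30.2 ± 0.208). The other 3 cell cycle lists each had an adjusted p of 0.911. Of 31 S phase and E2F target genes 2 rose and 1 fell, or 0 and 1 over the list alone (median -0.05). Of 11 replication-dependent histone genes 0 were called in either direction (median -0.11). Of 15 cyclins and CDK inhibitors of G1, 2 rose and 2 fell, or 2 and 4 over the list alone (median -0.13, called by fry at an adjusted p = 0.00707). Within these lists the transcription factor gene E2f2 had 45.5 ± 0.248 and 21.2 ± 2.48 FPKM, the CDK inhibitor gene Cdkn2d 70.2 ± 14.4 and 18.4 ± 3.04, and the CDK inhibitor gene Cdkn1a 15.2 ± 2.65 and 30.3 ± 2.09, all past the test. Of 14 BCL2 family genes, 2 fell, also over the list alone. They were the survival genes Mcl1 (123 ± 2.74 to 77.9 ± 3.18 FPKM) and Bcl2a1d (62.6 ± 5.30 to 41.6 ± 3.25), the latter with near-identical copies. The BCL2 family was not called by camera (median -0.27, adjusted p = 0.0741), though it was without DMSO replicate 1 (0.0449), without the limit on level (0.0344) and by fry (0.00565). Of 19 p53 target genes, 4 rose and 3 fell, also over the list alone (median 0.14, adjusted p = 0.102). Cdkn1a and Ei24 (43.9 ± 2.74 to 60.8 ± 3.13 FPKM) were among those that rose. Immediate early and heat shock genes, a sign of handling stress, were not called (13 genes, 1 higher and 2 lower, also over the list alone, median -0.14, adjusted p = 0.685).

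**Figure D3:**
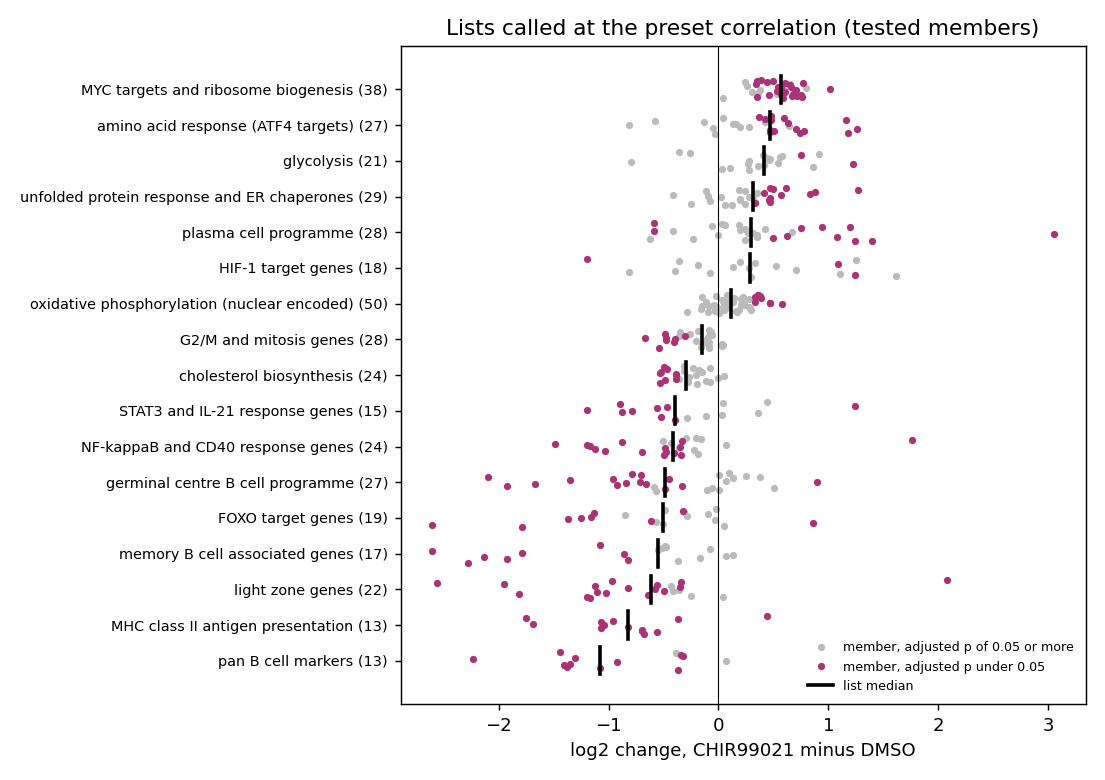
Log2 change (CHIR99021 minus DMSO, horizontal axis) of each tested member (points) of the 17 lists called with camera at the preset correlation, with the number tested in brackets, members at an adjusted p under 0.05 in colour and list medians as black bars. Medians run from -1.07 for pan B cell markers to 0.57 for MYC targets and ribosome biogenesis.

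Of the 32 lists tested, 17 were called, 7 higher and 10 lower, and fry called 19, and 14 lists were called by both. With the replicate block camera called 17 and fry 25. With a correlation estimated from the data 0 lists were called, and the smallest adjusted p was 0.284. Other splits of the same 6 libraries into 3 and 3 gave up to 16 called lists. With the replicate block more members passed in several lists that were not called: 5 S phase genes were higher and 7 lower, 5 G1 genes higher and 5 lower, 4 dark zone genes higher and 7 lower, and 8 p53 targets higher and 3 lower. In that fit 2 histone genes were higher and 1 lower, 2 immediate early genes higher and 5 lower, 1 interferon response gene higher and 6 lower, 1 glycogen gene higher and 1 lower, and 6 BCL2 family genes lower.

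Markers of other cell types had differing levels, and some were at 0 in all 6 libraries. Of 18 tested feeder fibroblast markers, 0 rose and 1, Thy1 (13.5 ± 6.17 to 5.26 ± 1.497 FPKM), fell, or 0 and 0 when adjusted over the list alone. The list was not called (median -0.37, adjusted p = 0.508). With the replicate block 10 fell and the list was called (adjusted p = 0.00218, and adjusted p = 0.432 with an estimated correlation). The fit without the block called it without CHIR99021 replicate 1 (0.0388), which leaves DMSO replicate 1, the library with the most feeder RNA, without its pair, and had a median of 0.091 without DMSO replicate 1. The call of Thy1 (adjusted p = 0.0278) was lost without DMSO replicate 3 (0.0541), CHIR99021 replicate 1 (0.0803) or CHIR99021 replicate 2 (0.0837). Col1a1, the most abundant of these markers, had 202, 69.2 and 36.2 FPKM in DMSO replicates 1, 2 and 3 and 165, 65.3 and 33.3 FPKM in CHIR99021 replicates 1, 2 and 3. Thy1 ran against this order and was highest in replicate 3 of both groups, at 20.6 FPKM in DMSO and 6.97 in CHIR99021. Its fall therefore need not reflect feeder RNA. The feeder markers summed to 0.0744%, 0.0318% and 0.0178% of all FPKM in the DMSO libraries. They summed to 0.0556%, 0.0245% and 0.0130% in the CHIR99021 libraries, alongside the falls of the B cell lists and the rises of the growth lists. Of the ligands expressed by the feeder cells, Tnfsf13b was the member tested. It had 3.92, 1.67 and 0.703 FPKM in DMSO replicates 1, 2 and 3 and 3.82, 1.54 and 1.38 in CHIR99021 replicates 1, 2 and 3. The CD40 ligand gene Cd40lg had 2.37, 0.550 and 0.382 FPKM in the DMSO libraries and 1.88, 0.357 and 0.138 in the CHIR99021 libraries. Within replicate 3, Tnfsf13b was thus higher and Cd40lg lower with CHIR99021. Myeloid markers were not called as a list (6 genes, 2 lower, also over the list alone, median -0.57, adjusted p = 0.133, or 0.0446 by fry). Itgam had 5.34 ± 0.791 and 1.42 ± 0.525 FPKM, while Cybb had 60.4 and 61.9. Of the 16 myeloid markers in the list, 6 were tested. Among those not tested, Cd14 was at 0 in all 6 libraries. Csf1r had 0.0730 and 0.0189 FPKM in DMSO and CHIR99021, and S100a8 had 0 and 1.26 ± 1.11. Of the T cell markers, Cd3e was listed at 0 in all 6 libraries. Cd3d (0.0976 and 0.0299 FPKM in DMSO and CHIR99021), Cd4 (0.0789 and 0.0257) and Cd8a (0 and 0.0113) were near 0. Of the 4 tested members, Zap70 rose from 0.793 ± 0.227 to 5.35 ± 0.712 FPKM (adjusted p = 0.000583) and Lat fell from 2.84 ± 0.454 to 1.498 ± 0.431 FPKM (adjusted p = 0.0457). The call of Lat was lost without DMSO replicate 1 (0.122), DMSO replicate 3 (0.121), CHIR99021 replicate 1 (0.111) or CHIR99021 replicate 2 (0.125). Cd2 (48.3 and 31.6 FPKM) and Lck (14.4 and 12.2 FPKM) did not pass. Ribosomal protein genes took 33.8%, 29.8% and 32.6% of all FPKM in DMSO replicates 1, 2 and 3 and 37.4%, 33.1% and 36.6% in CHIR99021 replicates 1, 2 and 3.

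**Figure D4:**
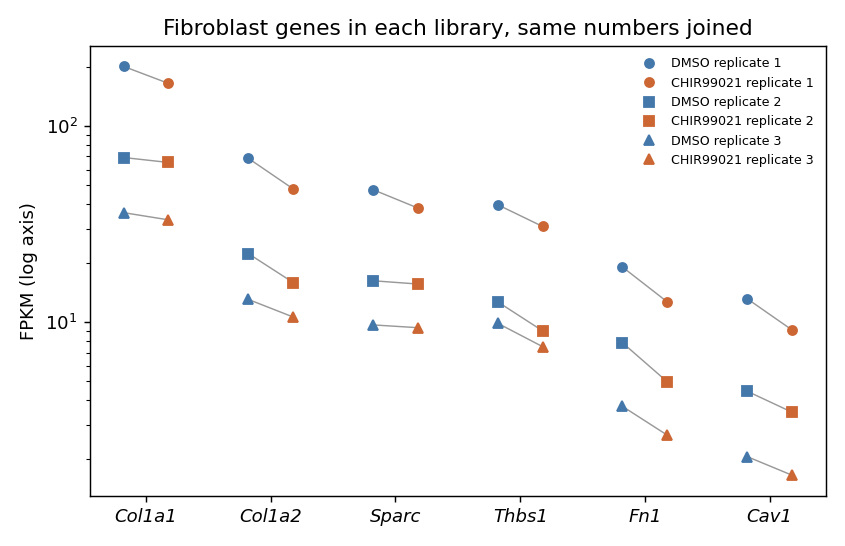
FPKM (log axis) of 6 fibroblast genes in each library, with colours for treatment, marker shapes for replicate number and lines joining libraries of the same number. Col1a1 ranges from 36.2 to 202 FPKM over the DMSO libraries, and the CHIR99021 library lies below the DMSO library of the same number for Col1a1 in 3 of 3 pairs.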

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

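The feeder covariate, leaving out both libraries of a number, and the GC content and length correction were chosen after seeing the data, and the other settings before. Of 113 named genes that were called, 101 stayed called in every setting with all 6 libraries, 90 in every fit without a single library, and all 113 kept their direction throughout. Of 17 called lists, 13 stayed called in every setting with all 6 libraries other than the estimated correlation, 13 in every fit without a single library, and all 17 kept their direction. The causes of the changes below were not tested, except that a stricter threshold on the adjusted p leaves fewer calls by construction. Fewer samples did not always leave fewer calls. Genes changed at least 2-fold numbered 447 without DMSO replicate 2, against 379 with all 6 libraries. Sequencing depth limits what can be seen for genes of low level such as Axin2. Genes changed by 0.5 on the log2 scale were rarely recovered in a simulation without the pairing or the block. That simulation held far fewer changed genes than the data, so it does not give the recovery at this size in these libraries.

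The replicate block, which follows the pairing of the libraries, called 4321 genes, 1855 higher and 2466 lower, and 10 key genes. It ended the STAT3 and IL-21 call (adjusted p = 0.0910), added the feeder list (0.00218), turned the cyclin and CDK inhibitor list in camera (median -0.13), and changed no other list call and no other call of a named gene than Bcl6, Ccnd2, Ctnnb1 and Xbp1. With the block and the GC content and length correction, 4378 genes were called, 1839 higher and 2539 lower, and 11 key genes, and camera's direction turned for the immediate early list, which was not called and had a median of -0.12. A threshold of 0.01 left 920 genes. A pseudocount of 5 left 159 genes changed at least 2-fold, 28 higher and 131 lower, and a limit of 5 FPKM left 61 higher. Quantile scaling called 1232 genes higher. Median-of-ratios, upper-quartile and quantile scaling called 2207, 2289 and 2406 genes in all, with 46.0%, 48.7% and 51.2% higher against 37.9%. The median of all genes moved from -0.04 to at most 0.03 under scaling. Xbp1 was called with each of these scalings (adjusted p = 0.0363, 0.0224 and 0.0252), and Ctnnb1 with library weights and with the feeder covariate. With an estimated correlation 0 lists were called, and with fry 19. Without a filter on level 20 lists were called, with the GSK3 complex (0.0215), BCL2 family (0.0344) and Wnt target lists (0.0375) added. The GC content and length correction ended the STAT3 and IL-21 call (0.118, or 0.267 with the block), and library weights and the feeder covariate ended the HIF-1 call.

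The lists whose direction turned in camera's test, which need not follow the sign of the median, were not called in either state. The S phase list had medians of -0.010, 0.0044 and 0.0037 with the 3 scalings and -0.033 with library weights, against -0.05. The histone list had 0.053 without a filter and 0.069 with the feeder covariate, against -0.11. The feeder list had 0.070 with its own level as covariate, which sets its mean change near 0 by construction. The cyclin and CDK inhibitor list had -0.13 with the feeder covariate and -0.053 with the GC content and length correction, with or without the block, while its mean without either was 0.02, so that its median, mean and test differed in sign.

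Without single libraries or both of a number, 187 to 1983 genes changed, 52 to 708 higher and 135 to 1275 lower, and 151 to 447 changed at least 2-fold, 40 to 115 higher and 111 to 332 lower. The lowest values came without both libraries of replicate 3, where 187 genes changed. Leaving out both libraries of replicate 1 or 2, with as many libraries kept, left 1088 and 1337. Without replicate 3 the calls of 72 named genes were lost, against 21 and 18 without replicates 1 and 2. Key genes called fell from 6 to 4 without replicate 3. Leaving out DMSO replicate 3, CHIR99021 replicate 2 or CHIR99021 replicate 3 alone left 1310, 1410 and 1061. Over these fits Myc ranged from -0.13 to 0.21. List medians ranged from -0.16 to -0.049 for cyclins and CDK inhibitors, -0.10 to -0.059 for dark zone genes, -0.82 to 0.091 for feeder markers, -0.10 to -0.041 for glycogen metabolism, -0.30 to 0.0092 for immediate early genes, -0.14 to 0.015 for lysosome genes, -0.42 to 0.19 for histones and -0.12 to 0.048 for S phase genes. Calls that a single library ended were those of the HIF-1, glycolysis, oxidative phosphorylation and STAT3 and IL-21 lists (given with each list), and of 13, 8 and 18 named genes for DMSO replicates 1, 2 and 3 and 13, 12 and 20 for CHIR99021 replicates 1, 2 and 3. Leaving out both libraries of a number ended the HIF-1 call for replicate 1 (0.131), the G2/M (0.0507) and STAT3 and IL-21 calls (0.0607) for replicate 2, and the latter for replicate 3 (0.0658). Rescaling without immunoglobulin segments was not run, since it would remove none of the genes used, nor were count-based tests, since the values are FPKM.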

Other observations

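Beyond the lists fixed beforehand, 23 gene families were chosen after the data were seen and tested with camera, adjusted over the 23. At the preset correlation 14 were called, 12 higher and 2 lower, and 9 were not, and with an estimated correlation 0 were called (smallest adjusted p = 0.329). Host genes of small nucleolar RNAs rose for 8 of 10 members with 0 lower (median log2 change 0.94, adjusted p = 1.10e-05, and adjusted p = 0.329 with an estimated correlation). Snhg6 had 66.0 ± 2.79 and 147 ± 10.4 FPKM in DMSO and CHIR99021 (SD, n = 3, limma adjusted p = 0.000431) and Snhg5 41.4 ± 5.56 and 103 ± 13.5 (0.00073), while Gas5 had 21.2 ± 10.2 and 38.4 ± 18.1 and did not pass (0.157). All 8 chaperonin subunit genes rose, which fold actin and tubulin among other proteins (median 0.44, adjusted p = 2.91e-05, and 0.329 as the adjusted p with an estimated correlation), with Cct2 at 259.6 ± 14.9 and 369.7 ± 19.1 FPKM. Cytosolic aminoacyl-tRNA synthetase genes rose for 11 of 18 (median 0.39, adjusted p = 2.87e-06). Genes of purine and pyrimidine synthesis rose for 7 of 15 (median 0.47, adjusted p = 1.23e-05), such as Impdh2 (306 ± 15.5 and 473 ± 49.2 FPKM). Lists fixed beforehand hold 5 of the 18 synthetase genes and 2 of the 15 purine and pyrimidine genes. The estimated correlation gave an adjusted p = 0.329 for both of these families. Of 82 cytosolic ribosomal protein genes 3 rose, or 51 with the replicate block (median 0.17, adjusted p = 2.17e-05), and an adjusted p = 0.691 with an estimated correlation. Their call was lost under quantile scaling (adjusted p = 0.0698), while the median of each of these families stayed above 0 under all 3 scalings.

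Among surface and signalling genes, 6 of 8 GIMAP genes, GTPases of lymphocytes, fell and 0 rose (median -0.48, adjusted p = 0.00347, and adjusted p = 0.329 with an estimated correlation), with Gimap8 at 25.5 ± 1.95 and 14.6 ± 0.703 FPKM. The family median stayed below 0 under all 3 scalings. Semaphorins and plexins fell for 5 of 11 (median -0.71, adjusted p = 0.0390, 0.153 with the replicate block, and adjusted p = 0.329 with an estimated correlation), among them Sema4b (26.8 ± 2.34 and 10.5 ± 1.66 FPKM) and Sema7a (47.2 ± 6.90 and 22.7 ± 1.53). Chemokine receptors were not called as a family (adjusted p = 0.226) and moved apart: Ccr6 and Ccr1 fell, while Cxcr7, Cxcr4, Ccr4 (0.499 ± 0.177 and 2.99 ± 0.289 FPKM) and Ccr10 (1.62 ± 1.01 and 8.22 ± 4.08) rose, and Cxcr5 had 54.1 and 53.2. The receptor genes Pdcd1 (0.475 ± 0.426 and 2.74 ± 0.713 FPKM, adjusted p = 0.00817) and Tigit (1.86 ± 0.797 and 6.09 ± 2.30, adjusted p = 0.0235) rose and were singled out after their values were seen.

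The tests of the Myc level, of other cell types, of an equal loss and of shared feeder RNA were chosen after the result was seen. Of 38 MYC target and ribosome biogenesis genes 25 rose, while Myc did not pass the test. Over the 3 scalings the lowest median of the list was 0.611 (largest adjusted p = 3.41e-11), and after the GC content and length correction it was 0.589 (adjusted p = 2.11e-14, and 5.86e-16 with the replicate block), which argues against scaling, GC content and length as the whole cause. With an estimated correlation the list had an adjusted p = 0.338, or 0.334 with the block. The list's median lay 3.36 standard errors above the change of Myc, which argues against a rise of the Myc transcript at 36 h as large as that of the list. A smaller rise stays open, since the change of Myc was 0.05 ± 0.16 (SE), and an earlier rise was not measured. GSK3 is known to mark MYC protein for degradation, so a more stable MYC protein is a hypothesis that these data do not test, and the level and half-life of MYC protein with and without CHIR99021 would test it.

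Of 13 pan B cell markers 11 fell and 0 rose, of 13 MHC class II genes 12 and 1, and of 22 light zone genes 16 and 1. Of 28 plasma cell genes 9 rose and 2 fell, or 17 and 4 with the replicate block. After the GC content and length correction the largest adjusted p of the 4 lists was 0.00037 at the preset correlation. Without that correction their adjusted p was 0.284, 0.367, 0.284 and 0.338 with an estimated correlation, for pan B cell markers, MHC class II, light zone and plasma cell genes. If cells of another type had replaced B cells, their markers would have risen. The feeder markers with all members above 0 had a median log2 change of -0.297, which argues against feeder cells in place of B cells. Most T cell and myeloid markers had a mean under 1 FPKM, where the pseudocount holds log2 changes near 0. Their medians (-0.0773 and -0.0569) therefore do not decide the question for T cells and myeloid cells. Cd3e was at 0 in all 6 libraries, while Zap70 rose from 0.793 to 5.35 FPKM. An equal loss of B cell RNA would move the pan B cell markers alike, yet the SD of their changes was 5.29 times their median standard error (0.649 against 0.123). That spread argues against an equal loss alone, while a shared loss beside changes of single genes stays open. A shift of the cells towards plasma cell differentiation may account for the changes of the 4 lists as a hypothesis. Whether all cells or a part of them shifted is open in these bulk libraries. Single-cell profiles of such cultures would test it.

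Fibroblast genes differed between replicate numbers and were lower with CHIR99021 in the fit with the block. Of 18 tested feeder markers, 16 (a share of 0.889) kept a single order of the replicate numbers in both groups, against a share of 0.0508 of all tested genes. A shared order restates the pattern, so it does not decide whether feeder RNA was carried into each library in differing amounts. The median stayed at -0.297 or lower under the 3 scalings with the block (largest adjusted p = 0.00188), which argues against scaling, while the blocked list had an adjusted p = 0.432 with an estimated correlation. The feeder cells bear the CD40 ligand, so a smaller carry-over and a smaller number of feeder cells in culture both stay open, and neither the number of feeder cells nor the purification was analysed here.

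The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed, 1 of the 10 splits, the real one, gave as many as 2164, and the highest of the others gave 1. For genes changed at least 2-fold, 1 of 10 gave as many as 379, and the highest of the others gave 1. For lists called, 1 of 10 gave as many as 17, and the others gave 5 to 16. The number of lists called at the preset correlation therefore barely sets the treatment apart from other groupings of these libraries. Among the 4 splits that part all 3 pairs, the others gave 0 genes and up to 14 lists, with 25 to 46 genes at an unadjusted p under 0.05 against 3613 in the real split by limma's test. Every other split puts libraries of both treatments in each group, so a treatment difference widens the spread within groups and lowers the gene counts. The gene counts of the other splits are therefore no measure of what chance gives.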
